A study of Homo sapiens with 5 samples.

How the data were processed

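ChIP-seq for PHF8 in THP1 cells was analysed from peak lists, 4 from single libraries (2 replicates each of PHF8AA and PHF8DD) and 2 pooled lists, 1 per group. Groups were taken from the genotype label and replicate numbers from the titles. The IgG library, labelled as PHF8AA IgG, entered only as the control behind the peak scores. FastQC 0.11.9, BWA 0.7.17, SAMtools 1.9 and MACS2 are named in the submitters' processing notes without their roles, and the build there is hg38. Peaks were called with MACS2 against IgG, per the file headers and peak names, which also carry the value 0.05, and every listed peak passed a q of 0.05. Trimming, duplicate removal and filters are not given in the sources used here.

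The deposited lists give for each peak a fold enrichment, which is the authors' ratio of summit height to background. They also give the deposited −log10 p and −log10 q of the caller and the summit position. The fold and the p of a peak were used only to describe, rank or filter peaks within a list. The lists give no read totals. Height and background at each summit were therefore solved from fold enrichment = (height + 1)/(background + 1) and the Poisson tail probability. The solved heights were whole multiples of 1 step per list, within a tolerance of 0.05 fragments, for 100% of the peaks of each list, against 12.8% to 18.3% (median over other steps), which passed the minimum of 90% set beforehand. The step gives the depth relative to the IgG library. The library-wide background was 10.1 fragments per position in 5 of the 6 lists, PHF8AA and PHF8DD alike, so that both groups were scored against the same control, and 9.92 in PHF8DD replicate 2, where IgG was scaled down to the smaller ChIP library. The pooled lists had a relative depth of 2.22 (PHF8AA) and 2.13 (PHF8DD), against 2.24 and 2.15 for the sums of their replicates, so they are calls on merged reads and not overlaps of the library lists. Relative depth spanned 1.19-fold and list length 52.9-fold.

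Peaks were compared by overlap of at least 1 bp against 1000 random placements of the shorter list on the same chromosomes, within the span of the annotation. No sequence was used, so placements could fall in assembly gaps, which lowers the random overlap slightly. Placements were also uniform and took no account of the clustering of peaks near gene ends. That lowers the random overlap further, by an amount not measured. Gene positions came from the RefSeq annotation of GRCh38.p14, the same build as hg38. It gives no strand, so the distance to a gene start fixed in the design was replaced by the distance to the nearer of the 2 ends of a gene, which counts some 3′ ends as well. Exons, introns and untranslated regions were not told apart for the same reason. GC content, CpG ratio, runs of N and repeat masking at peaks were not run. Overlaps, placements and gene counts used peaks on chromosomes alone, which leaves out 6 peaks of PHF8AA replicate 1 and 4 of the PHF8AA pooled list on a phage contig.

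Peak number was compared as the difference of group means of log2 peak number with an exact permutation test. Gene lists were tested with Fisher's exact test against the other genes among 19126 autosomal protein-coding genes, with Benjamini-Hochberg adjustment over 10 lists and both pooled lists, and the p-values describe these lists and not the groups. Fold enrichment of shared and other peaks was compared with 100000 permutations, and chromosomes with 10000 multinomial draws. The simulation against 1 control took as many best windows as each pooled list has peaks on chromosomes, because a first version with a score threshold made 0 calls. Intervals of shares are 95% Wilson intervals and cover counting error only. Genes were named by a rule written before the data were examined: in each pooled list the 12 peaks of highest fold enrichment within 1000 bp of a protein-coding gene, every gene of a fixed list with a pooled peak within 1000 bp, up to 10 regions present in all 4 libraries, the 5 highest peaks wherever they lie, and PHF8 and ESR1 as loci a construct could share reads with. Some results that this rule covers are not reported here. The HOXA cluster as a whole, the genes added by the 10000 bp window and the PHF8AA peaks without a PHF8DD counterpart were described outside that rule. Replicate numbers 1 and 2 occur in both groups, but nothing in the labels ties equal numbers to a shared day or culture, and 2 pairs are too few to tell from the data.

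Alternatives covered stricter peaks (−log10 q of at least 3, fold enrichment of at least 5), other definitions of overlap, lists of equal length, windows of 5000 and 10000 bp, protein-coding or all genes, single replicates, regions found in both replicates and each replicate left out. On simulated lists, the recovery of height returned the known value for 100% of 700 peaks. The overlap test found all 35 planted peaks, which were copied from the PHF8DD pooled list, and called 0 of 40 random lists. Those lists were placed uniformly like the placements, so this does not show how the test treats lists clustered near gene ends. The gene list test called 100% of 200 simulated lists with 6 of 30 genes planted and 2% of those with none. These calls used the raw p and genes drawn independently, so they do not give the power of the adjusted tests or for fewer genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.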

Results

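The series mapped the binding of PHF8, a histone lysine demethylase, by ChIP-seq (sequencing of DNA fragments that an antibody pulls down with the protein bound to them) in THP1, an established human monocytic leukaemia line that carries the MLL-AF9 fusion. Per the labels, cells were treated with 100 nM 4-OHT to induce either PHF8AA or PHF8DD. The labels do not spell out what AA and DD stand for, and the sample titles also carry the term PHF8WT. Each group had 2 replicate libraries, and 1 IgG library, labelled PHF8AA, served as the control for both groups. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical. The files held 1 peak list per library and 1 pooled list per group, 6 lists in all. The lists held 28 peaks for PHF8AA replicate 1, 299 for PHF8AA replicate 2, 298 for PHF8DD replicate 1 and 1480 for PHF8DD replicate 2. The pooled lists held 77 peaks for PHF8AA and 618 for PHF8DD. Relative to the IgG library, the depth solved from the peak scores was 1.15 and 1.08 for PHF8AA replicates 1 and 2, and 1.17 and 0.978 for PHF8DD replicates 1 and 2. All fold enrichments below are the authors' own values over the IgG background, and they rank peaks only within a list. Coordinates are 1-based on hg38.

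The first comparison asked which genes PHF8 occupied in each group. In the PHF8DD pooled list the peaks of highest fold enrichment lay in BAHCC1 (chromosome 17, 81395937 to 81397894, 5.65-fold) and INO80D, a subunit of the INO80 chromatin remodelling complex (chromosome 2, 206084971 to 206086291, 5.65-fold). Peaks in ZCCHC2 (5.36-fold), beside the predicted gene LOC124904588 on chromosome 1 (5.30-fold) and in SETD2, a histone methyltransferase (5.19-fold), came next. In the PHF8AA pooled list the highest values were at LRRC41 (chromosome 1, 46301826 to 46303165, 4.98-fold), at BAHCC1 (4.88-fold), at a site on chromosome 1 (144077128 to 144077882, 4.51-fold) 75410 bp from the nearest protein-coding gene end, and at INO80D (4.38-fold).

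Among peaks within 1000 bp of a protein-coding gene end, INO80D, LRRC41, PRCC and FBXW4 stood in the 12 highest of both pooled lists. BAHCC1 did so in the PHF8DD list alone, its PHF8AA summit lying 1135 bp from the gene end and so just outside the window. The PHF8DD list added SDC2, a cell surface proteoglycan (4.92-fold), CDK13, a transcriptional kinase (4.85-fold), NSMAF (4.84-fold), ZC3H7B (4.72-fold) and KCMF1 (4.68-fold). The PHF8AA list added NHLRC2 (3.64-fold), the transcription factor genes ZIC2 (3.57-fold), PRDM6 (3.57-fold) and IRX5 (3.42-fold), as well as GALNT7 (3.53-fold), RPS29 (3.49-fold) and the RNA polymerase III subunit gene POLR3C (3.45-fold). Each of these PHF8AA peaks also overlapped a peak of the PHF8DD pooled list, at 3.42-fold to 4.43-fold.

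A peak was present in all 4 library lists at 18 regions, and all 18 overlapped a PHF8DD pooled peak. Those of highest PHF8DD pooled fold enrichment included peaks in BAHCC1, CUL1, PRCC, SDC2, LRRC41, FBXW4 and ZC3H7B, 25235 bp from METTL2B, and in SMARCA2. CUL1, the scaffold of SCF ubiquitin ligases (chromosome 7, 148698797 to 148699942), reached 5.10-fold, and SMARCA2, an ATPase of the SWI/SNF complex (chromosome 9, 2015674 to 2017534), reached 4.46-fold. At these 18 regions the fragment number at the summit, divided by relative depth, had a median of 41.6 in PHF8AA replicate 1, 49.5 in PHF8AA replicate 2, 51.0 in PHF8DD replicate 1 and 61.3 in PHF8DD replicate 2. Against PHF8AA replicate 1 it was higher in PHF8DD replicate 1 at 14 of 18 regions and in PHF8DD replicate 2 at 18. Against PHF8AA replicate 2 it was higher at 9 and 13 regions. Within groups, replicate 2 was higher than replicate 1 at 17 regions in PHF8AA and 18 in PHF8DD.

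The central comparison set PHF8DD against PHF8AA. Nearly all PHF8AA sites were also PHF8DD sites: 69 of the 73 PHF8AA pooled peaks on chromosomes (94.5%) overlapped a PHF8DD pooled peak by at least 1 bp. The exceptions lay at HOXA9 (chromosome 7, 27166149 to 27166785, 3.08-fold), 35079 bp from EBLN1 (3.57-fold), 46815 bp from ANXA2R (2.75-fold) and at the predicted gene LOC107987020 (2.35-fold). The genes of any type nearest to the EBLN1 and ANXA2R sites were LOC100130992 (1022 bp) and LOC105374746 (281 bp). The EBLN1 site was a peak in PHF8DD replicate 2, and the LOC107987020 peak lay in a merged region (chromosome 9, 62801132 to 62802994) that had a peak in all 4 libraries. The share depends on the unequal lengths of the lists: with the 73 peaks of highest fold enrichment of each list it was 38.4% (permutation test by placement, p = 0.001). Random placements of the PHF8AA list gave a mean overlap of 0.027 peaks and at most 1 (permutation test by 1000 placements, one-sided, p = 0.001, the smallest they can give). Placements were uniform along chromosomes, while most peaks of both pooled lists lay near gene ends. Lists with that preference alone could exceed them, so the test cannot show sharing beyond it. Of the 50 protein-coding genes with a PHF8AA pooled summit within 1000 bp of an end, 49 also had a PHF8DD pooled summit there, against 1.35 for independent gene sets and at most 8 in 1000 random gene sets. The random sets were drawn from all 19126 genes, active or not, which is a similar limit. All lists were called against the same IgG background. In 20 simulations of unchanged libraries against 1 control, the 73 and 618 best windows shared 0, but the simulated background was uniform and so cannot show what a control that misses local background would do. Part of the overlap may come from that control. Among the 35 PHF8AA pooled peaks whose background was the library-wide one, 34 overlapped, a setting not planned beforehand. Local background missed by the control would also leave peaks at the library-wide value, so this count cannot decide the question.

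In the other direction, 70 of the 618 PHF8DD pooled peaks (11.3%) overlapped a PHF8AA pooled peak. BAHCC1, INO80D, SETD2 and ZCCHC2 were among the shared sites. KCMF1, CEBPD (4.15-fold), KDM3B (3.71-fold), JAK1 (3.25-fold) and TRIM25 (3.17-fold) had a PHF8DD pooled peak and no PHF8AA pooled peak. KCMF1, CEBPD and KDM3B were nevertheless peaks in PHF8AA replicate 2. Within the PHF8DD pooled list, the shared peaks had a median fold enrichment of 3.80 and the other 548 peaks one of 3.29, a difference of 0.509 (permutation test, two-sided, p = 1e-05, the smallest it can give). Peaks high in 1 list are more likely to pass the threshold in the other, so this direction does not set the groups apart.

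The number of peaks was higher in PHF8DD. The mean of log2 peak number was 9.38 ± 1.63 (SD, n = 2) in PHF8DD and 6.52 ± 2.42 (SD, n = 2) in PHF8AA, a difference of 2.86, or 7.26-fold. This difference lay between the replicate differences of the 2 groups: replicate 2 exceeded replicate 1 by 10.7-fold in PHF8AA and by 4.97-fold in PHF8DD. The exact permutation test (two-sided) gave p = 0.667, and 2 libraries against 2 cannot go below 0.333. Without PHF8AA replicate 1 the difference was 1.15, and without PHF8AA replicate 2 it was 4.57; without PHF8DD replicate 2 it was 1.70.

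**Figure D1:**
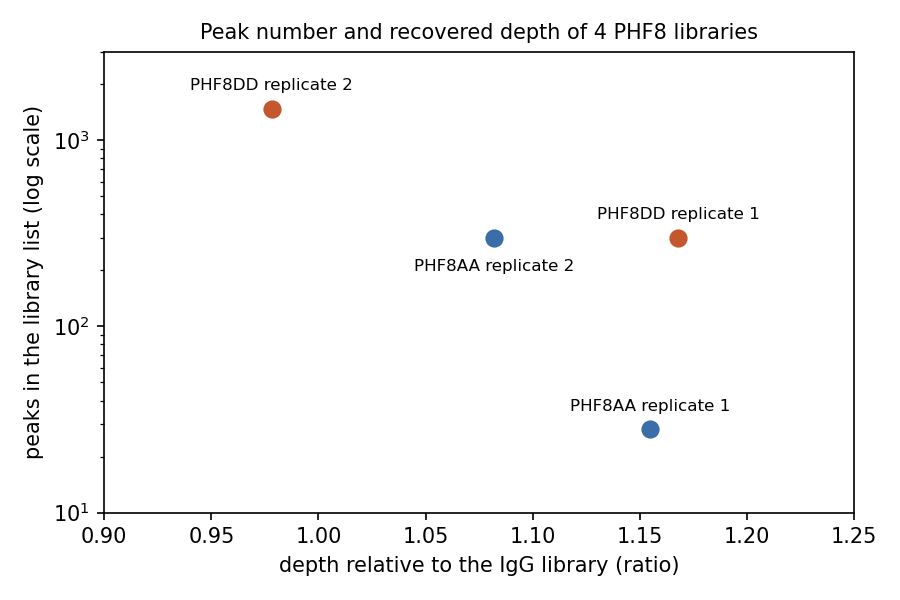
Number of peaks in each library list (vertical axis, log scale) against sequencing depth relative to the IgG library (horizontal axis, ratio), with 1 point per library, PHF8AA in blue and PHF8DD in orange. The library with the lowest relative depth, 0.978, had the longest list, 1480 peaks, and the lists of PHF8AA replicate 2 and PHF8DD replicate 1 were of nearly equal length, 299 and 298.

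Between single libraries the shorter list lay mostly inside the longer one. Of the 22 PHF8AA replicate 1 peaks on chromosomes, among them LRRC41, SDC2 and CUL1, 21 overlapped PHF8AA replicate 2, 18 overlapped PHF8DD replicate 1 and 22 overlapped PHF8DD replicate 2. Of the PHF8AA replicate 2 peaks, 282 of 299 (94.3%) overlapped PHF8DD replicate 2, as did 287 of the 298 PHF8DD replicate 1 peaks (96.3%). The lists of near-equal length shared less: 147 of the 298 PHF8DD replicate 1 peaks (49.3%) overlapped PHF8AA replicate 2. These shares depend on list length. With the 22 peaks of highest fold enrichment of each list, this pair shared 31.8%, PHF8DD replicates 1 and 2 shared 40.9%, and PHF8AA replicate 2 shared 22.7% with each of PHF8AA replicate 1 and PHF8DD replicate 2. PHF8AA replicate 1 then shared 36.4% with PHF8DD replicate 1 and 31.8% with PHF8DD replicate 2. In each of the 6 pairs the overlap exceeded every random placement (permutation test by placement, one-sided, adjusted p = 0.001 over the 6 pairs by Benjamini-Hochberg). These placements too were uniform and ignored the clustering of peaks near gene ends. Of the 1506 merged regions, 136 were in both PHF8DD libraries and no PHF8AA library, none were in both PHF8AA libraries alone, and 123 were in both replicate 2 libraries and no replicate 1 library.

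The HOXA cluster was compared next, because the series title concerns self-renewal in leukaemia and HOXA genes are known targets of MLL fusions. HOXA10 and HOXA11 carried a peak in all 4 libraries. The HOXA10 peak lay inside the gene (chromosome 7, 27172795 to 27173961 in the PHF8DD pooled list) at 3.73-fold in the PHF8AA and 3.33-fold in the PHF8DD pooled list. The HOXA11 peak (27184073 to 27184939 in the PHF8DD pooled list) stood at 3.77-fold and 3.33-fold. HOXA13 had a peak in PHF8AA replicate 2 and both PHF8DD libraries (3.97-fold in the PHF8DD pooled list), and HOXA5 in both replicate 2 libraries. Over the whole cluster of 11 genes (27092993 to 27200091) there were 2 peaks in PHF8AA replicate 1, 7 in PHF8AA replicate 2, 4 in PHF8DD replicate 1 and 7 in PHF8DD replicate 2.

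**Figure D2:**
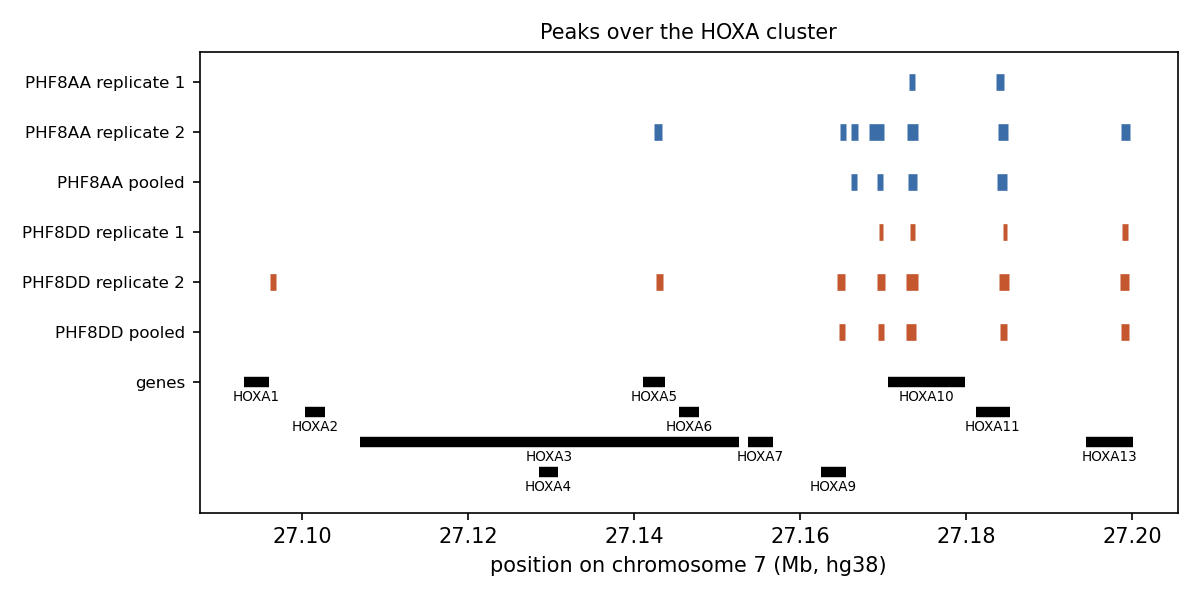
Map of the HOXA cluster on chromosome 7 (horizontal axis, Mb, hg38) with each list's peaks as bars drawn to scale, PHF8AA in blue and PHF8DD in orange, and genes as black bars, staggered so that overlapping genes can be told apart. The peaks in HOXA10 and HOXA11 are present in all 6 lists, and the peak in HOXA13 is missing from PHF8AA replicate 1 and the PHF8AA pooled list.

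HOXA9 and HOXA10 belong to the fixed list of 30 genes of the MLL-AF9 and stem cell programme. Within 1000 bp of a gene end, 3 of its members had a PHF8DD pooled peak. These were GFI1, a transcriptional repressor of blood stem cells (2.66-fold), HOXA9 (2.35-fold) and HOXA10 (3.50-fold). HOXA9 alone had a PHF8AA pooled peak in that window, which did not overlap the PHF8DD one. The HOXA10 peak lay outside the gene and was also a PHF8AA pooled peak (3.28-fold), with its summit at 1007 bp. GFI1 had a higher peak in both pooled lists, at 1354 bp in PHF8DD (4.22-fold) and 1395 bp in PHF8AA (3.93-fold). Fisher's exact test (one-sided) gave an adjusted p of 0.378 for each group. In the second count, with 10000 bp, 7 members had a PHF8DD pooled peak against 1.12 expected (Fisher's exact test, adjusted p = 0.000951): GFI1, HOXA7, HOXA9, HOXA10, MYB, MYC and ZEB2. For PHF8AA it was 4 members against 0.116 expected (exact test, adjusted p = 0.000105): GFI1, HOXA7, HOXA9 and HOXA10. In MYB the summit lay 1252 bp from the gene end (chromosome 6, 135181567 to 135183208, 3.45-fold), in MYC 2753 bp (chromosome 8, 127736871 to 127738820, 2.96-fold) and in ZEB2 2629 bp (2.83-fold). HOXA genes shared peaks in this window, and without the HOXA genes the raw p was 0.0112 for PHF8DD (4 of 24 genes) and 0.0855 for PHF8AA (GFI1 alone), a calculation chosen after seeing the data.

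The title also concerns the type I interferon response. Of the 48 interferon response genes fixed beforehand, RSAD2, which encodes the antiviral protein viperin (chromosome 2, 6865246 to 6865848, 2.66-fold), and TRIM25, a ubiquitin ligase in RNA sensing (3.17-fold), had a PHF8DD pooled peak within 1000 bp. That was 2 genes against 1.29 expected (Fisher's exact test, one-sided, p = 0.372, adjusted p = 1). None of the 48 had a PHF8AA pooled peak. Of the 29 autosomal genes of nucleic acid sensing and interferon signalling, CGAS, the cytosolic DNA sensor, had a peak in both groups (3.92-fold in PHF8DD and 2.76-fold in PHF8AA), and JAK1 and NFKB1 (3.29-fold) had one in PHF8DD. The 3 PHF8DD genes stood against 0.781 expected (raw p = 0.0422, adjusted p = 0.378 by Fisher's exact test). NFKB1 was a peak in PHF8AA replicate 2 and in both PHF8DD libraries, whereas RSAD2, TRIM25 and JAK1 were peaks in PHF8DD replicate 2 alone among the libraries. CGAS was a peak in the replicate 2 library of each group and in neither replicate 1 library.

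Among histone lysine methylation enzymes, EZH2, the methyltransferase of Polycomb complexes (3.04-fold), and KDM3B, a demethylase (3.71-fold), had a PHF8DD pooled peak within 1000 bp, 2 of 29 genes (Fisher's exact test, adjusted p = 0.631). Among the libraries EZH2 was a peak in PHF8DD replicate 2 alone. At 5000 bp KDM5B and SETD2 joined EZH2 and KDM3B, and the list did not pass (exact test, adjusted p = 0.112). At 10000 bp SETDB1 joined as well, 5 genes against 1.08 expected (exact test, adjusted p = 0.0270). That call was lost when each peak was given to its nearest gene alone, with 4 genes against 0.840 expected and an adjusted p of 0.0621 by the exact test, a setting chosen after seeing the data. Of the 26 autosomal myeloid differentiation genes, CEBPD had a PHF8DD pooled peak within 1000 bp, and CEBPA, the granulocyte-monocyte lineage factor, had one with its summit 1280 bp from the gene end (chromosome 19, 33300213 to 33302196, 4.81-fold). Ribosomal protein genes were represented by RPL7 (3.25-fold) and RPS29 (3.42-fold) in PHF8DD, 2 of 80 against 2.15 expected. Both summits lay outside these genes, at 175 and 246 bp, and nearer to RDH10 (39 bp) and LRR1 (16 bp). With each peak given to its nearest gene alone, 0 ribosomal protein genes had a PHF8DD pooled peak. The ZNF family had 10 of 505 genes with a PHF8DD pooled peak, against 13.6 expected, and ZNF639 alone with a PHF8AA one. No apoptosis, cell cycle or replication-dependent histone gene had a pooled peak within 1000 bp, although apoptosis genes such as BCL2 and MCL1 had a peak there in PHF8DD replicate 2. Of 643 tRNA, rRNA and other small structural RNA genes 2 had one in PHF8DD and 0 in PHF8AA. Over 10 gene lists and 2 pooled lists, 0 tests passed the adjusted threshold of 0.05 at 1000 bp by Fisher's exact test, and 2 had an unadjusted p under it, both in PHF8DD.

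Peaks of both groups clustered just inside genes, as at PRCC, where the PHF8DD summit lay 287 bp from the gene end, KDM3B (527 bp) and NFKB1 (504 bp). A gene end of the annotation lay within 1000 bp of 488 of the 618 PHF8DD pooled summits (79.0%, 95% Wilson interval 75.6 to 82.0) and of 52 of the 73 PHF8AA pooled summits (71.2%, 59.99 to 80.3). Random placements gave 6.33% and 5.92%, and none of 1000 reached the observed share (permutation test by placement, one-sided, p = 0.001 for each list, the smallest they can give). Of the PHF8DD pooled summits within 2000 bp of a protein-coding gene end, 493 of 538 (91.6%) lay inside the gene, and in PHF8AA it was 48 of 56 (85.7%). The median distance was 514.5 bp in PHF8DD and 588.5 bp in PHF8AA. Gene ends were near 72.9% of the PHF8DD peaks shared with PHF8AA and 79.7% of the other PHF8DD peaks (Fisher's exact test, two-sided, p = 0.212). With protein-coding genes alone that gap was -14.3 percentage points and passed the threshold (exact test, p = 0.0152).

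**Figure D3:**
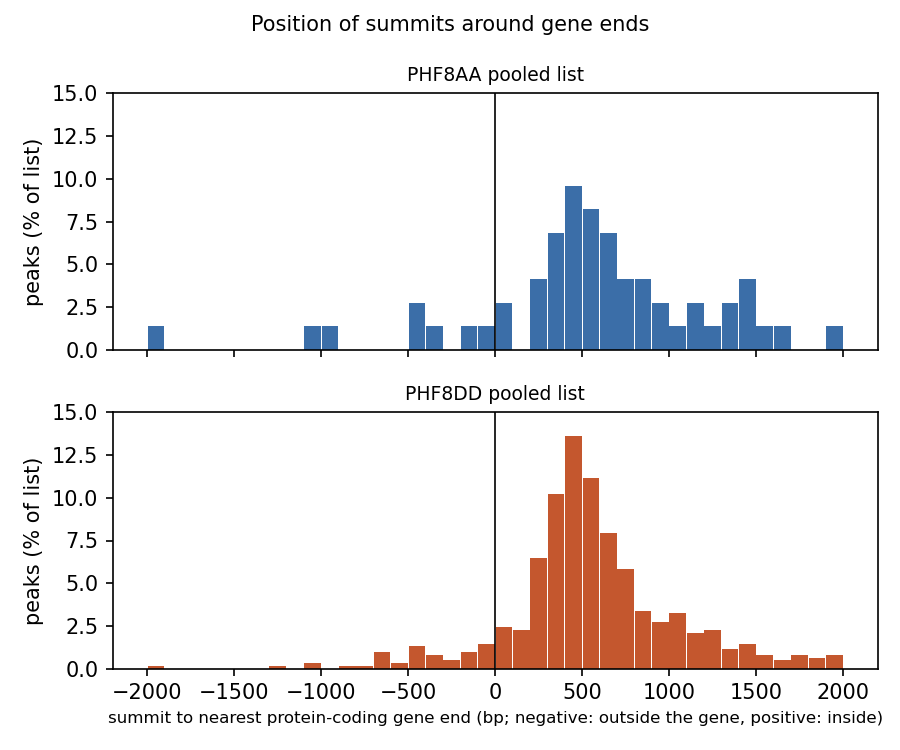
Percentage of each pooled list's peaks (vertical axis) by the signed distance of the summit from the nearest protein-coding gene end in 100 bp bins (horizontal axis, bp; positive values are inside the gene), PHF8AA in blue and PHF8DD in orange. The highest bin in both lists spans 400 to 500 bp inside the gene and holds 9.59% of PHF8AA and 13.6% of PHF8DD peaks.

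The spread over chromosomes was uneven in the longer lists. In PHF8DD replicate 2, chromosome 18 held 42 peaks where its number of protein-coding genes predicts 20.9, and chromosome 8, with SDC2, NSMAF and CEBPD, held 106 against 55.3. Chromosome 19 held 52 against 112.3 and chromosome 12 held 31 against 79.2. These examples depend on gene number as the baseline. By span, chromosome 19 held its 52 peaks on 58.6 Mb and chromosome 18 its 42 on 80.2 Mb, the reverse order. Chromosome 8 held 106 on 145.0 Mb and chromosome 12 held 31 on 133.2 Mb, the same order. This list departed less from chromosome length (chi-square 94.9) than from gene number (chi-square 257.6). The PHF8DD pooled list departed from chromosome length (chi-square 67.1, multinomial test with 10000 draws, p = 0.0001, the smallest it can give), and the PHF8AA pooled list did so with chi-square 36.0 and p = 0.0255. All peaks on chromosomes lay on the 22 autosomes, so PHF8 itself, on chromosome X, was not analysed here. ESR1 on chromosome 6 (151656672 to 152129619), examined because 4-OHT-controlled constructs commonly carry part of this receptor gene, had 0 peaks in its body or within 10000 bp in each of the 6 lists.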

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

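The tests of explanations in this part were chosen after the results were seen. PHF8AA replicate 1 held 6 peaks on the contig named LAMBDA (a bacteriophage genome), and the PHF8AA pooled list held 4. The other library lists and the PHF8DD pooled list held 0, and without these peaks the difference of log2 peak number was 3.03 in place of 2.86. They were singled out because they lie in data outside the human chromosomes. In PHF8AA replicate 1 their fold enrichment over IgG ran from 1.77 to 6.58, with 307 to 780 fragments at the summit.

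Phage DNA in that library alone is argued against by the IgG background on the contig, which was at least 82 fragments per position, 8.09 times the library-wide value. Loss of genomic reads to the phage, as a reason for the short list of PHF8AA replicate 1, is argued against by the size of the signal only if duplicates were kept. The highest summit extended over the contig up to the last peak then comes to 0.0567% of the library. Removal of duplicates, which is not known, would cap the heights. The contig beyond the last peak is left out too, so the estimate is no upper limit. At the 4 contig peaks of the PHF8AA pooled list the summits held 455, 442, 760 and 799 fragments. PHF8AA replicate 1 alone held 445, 429, 743 and 780 there. PHF8AA replicate 2 thus added few fragments on the contig, unless duplicates were removed on merging. Why the 2 libraries differed there, and what set the PHF8DD libraries apart, stays open, and no biological explanation was tested.

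The larger number of peaks in PHF8DD is the pattern the design asks about, and sites such as JAK1 and TRIM25 rest on it. Depth is argued against, because the library with the most peaks had the lowest relative depth, 0.978. Enrichment that differs between preparations of 1 group remains a candidate explanation: replicates 1 and 2 of a group differed by a mean of 2.86 in log2 peak number, as much as the groups did. A difference between PHF8AA and PHF8DD cells also stays open, since the exact permutation test gave p = 0.667 and 2 libraries against 2 cannot pass the threshold. The only IgG library was labelled PHF8AA, so PHF8DD had no control of its own group. The design cannot tell this apart from the group.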

How the results depend on the processing

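Of 248 alternative values for 36 results, 232 kept their direction and their side of the threshold, 0 reversed, 9 passed the threshold only under the alternative and 7 moved. All 38 alternatives of the overlaps exceeded the random placements, with shares from 22.7% (the 22 highest peaks of each list) to 100%. All of them used uniform placements, so none addresses the clustering of peaks near gene ends. The log2 ratio of peak number ranged from 1.15 to 4.57 when a library or a replicate number was left out. With the replicate number as a block (replicate block) it was 2.86 ± 0.781 (SD of the 2 differences), equal to the unpaired value by construction, and the numbers are not known to pair the libraries. The pooled lists gave 3.005.

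The gap in gene-end share between shared and other PHF8DD peaks was -14.3 percentage points with protein-coding genes only, past the threshold. With single replicates in place of the pooled lists it ranged from -7.78 to -6.71, and replicate 2 passed (Fisher's exact test, p = 0.00319). The causes were not tested. The number of gene lists past the threshold was 0 at 1000 bp, 1 in PHF8AA and 1 in PHF8DD at 5000 bp, and 1 and 2 at 10000 bp. With 1 gene per peak at 10000 bp, a setting chosen after seeing the data, it was 1 and 1. In each of these the MLL-AF9 and stem cell programme list passed, with a wider window adding members by construction. Solving heights without the +1 left 17.1% whole in place of 100%, since the caller adds it. GC content, repeats and runs of N, and the alternatives for the sequence of peaks, were not run. With relative depths near 1, a site missing from a short list is below its detection limit and not shown to be unbound.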

Other observations

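PHF8DD replicate 2, the longest list, held more fixed-list genes within 1000 bp than the pooled lists, named here after their values were seen. Of the interferon response list it held ADAR (3.29-fold), IFIT5 (3.39-fold), PSMB9 and TAP1 (a shared peak, 2.55-fold) besides RSAD2 and TRIM25. That was 6 genes against 3.24 expected (Fisher's exact test, raw p = 0.102, adjusted p = 0.511 over the 40 tests of the library lists). The test counts the peak shared by PSMB9 and TAP1 for both genes. Of the myeloid list it held CEBPA, CEBPD, IRF8 (2.82-fold) and ELANE, 4 against 1.75 expected (exact test, raw p = 0.0943, adjusted p = 0.511). Of the MLL-AF9 list it held BCL2, CDK6, DOT1L, HOXA5, HOXA9 and HOXA10, 6 against 2.02 expected (exact test, raw p = 0.0136, adjusted p = 0.273). None of these 3 lists passed the adjusted threshold in any library.

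Homeobox and other developmental transcription factor families, a list of 231 genes chosen after names such as ZIC2 and IRX5 were seen, took a higher share of PHF8AA pooled genes than of genes with a PHF8DD pooled peak only. Within 1000 bp it was 4 of 50 genes (8%; DMRTA2, HOXA9, IRX5 and ZIC2) against 9 of 466 (1.93%; Fisher's exact test, two-sided, p = 0.0290). Within 5000 bp it was 8 of 67 against 13 of 592 (exact test, p = 0.000526), with neighbours such as IRX3 and IRX5, ZIC2 and ZIC5, and HOXA9 to HOXA11 counted apart. The whole PHF8DD pooled list, which holds 49 of those 50 PHF8AA genes, was also above other genes, with 13 of 515 (2.52%) against 1.17% within 1000 bp (exact test, p = 0.0118) and 21 of 659 within 5000 bp (exact test, p = 5.30e-05). Between the lists of near-equal length it was 4 of 111 genes found in PHF8AA replicate 2 and not PHF8DD replicate 1, against 2 of 142 the other way within 1000 bp (exact test, p = 0.409). Within 5000 bp it was 7 of 134 against 0 of 165 (exact test, p = 0.00332), among them HOXA5 and HOXA6. Because the list was chosen from these names, the p-values describe the pattern and do not test it independently.

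The background solved from the scores was far above the library-wide value at 5 PHF8DD replicate 2 peaks between 40040761 and 40477750 on chromosome 1, near CAP1, RLF, ZMPSTE24, SMAP2 and ZFP69, at 6.47 to 9.31 times the library-wide value. The ZMPSTE24 peak stood at 7.44 times in PHF8AA replicate 2 and 7.50 times in PHF8DD replicate 1. On chromosome 8 the background exceeded the library-wide value at 100% of the 106 PHF8DD replicate 2 peaks, with a median of 1.36 times, and on chromosome 12 at 3.23% of 31.

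The uneven spread over chromosomes in PHF8DD replicate 2 was weighed with tests chosen after it was seen. More copies of some chromosomes in this line might raise peak numbers, as on chromosome 8. Chromosome 18 had a median background at the library-wide value and 2.01 times its gene-based number of peaks (adjusted binomial p = 0.000118). That excess holds against gene number alone. The list departed less from chromosome length (chi-square 94.9) than from gene number (chi-square 257.6). Chromosome 18 therefore cannot decide whether copy number is the whole cause. Fewer peaks per gene where genes are dense remains a candidate explanation: over the 22 autosomes, peaks per gene fell with genes per Mb (Spearman's rho = -0.845, permutation p = 1e-05, Pearson's r = -0.632, permutation p = 0.000420, and r = -0.806 without chromosomes 17 and 19). Gene number enters both axes, and peaks drawn in proportion to gene number gave rho between -0.432 and 0.432 in 95% of 10000 draws. Peaks spread in proportion to chromosome length would also give fewer peaks per gene where genes are dense. Such draws were not made, so rho cannot separate gene density from length. Whether base composition lies behind gene density was not tested.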
